A study of Mus musculus with 15 samples.

How the data were processed

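RNA of pericytes isolated from mouse kidney was measured on 15 Illumina MouseRef-8 V2 BeadChip arrays, each of which carries oligonucleotide probes on coloured beads. Per the labels, the cells came from mice that carry a Foxd1 driver, a tdTomato reporter and a Col1a1-linked green reporter. RNA was extracted at once after isolation with Trizol and column cleaning that included DNase I, its quality was checked on a Bioanalyser, and biotin-labelled cRNA was made with an Ambion kit, per the labels' protocols. How the pericytes were isolated and gated is not given in the sources used here. The samples were grouped by the labels into uninjured control kidneys and kidneys at 2, 7, 28 and 56 days after ischemia-reperfusion injury, with 3 samples per group.

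The authors exported the arrays from the GenomeStudio gene expression module, version 1.9.0, per the file headers. The deposited intensity of a probe is the mean signal of its beads on a linear scale, without background subtraction and without normalization in 1 report and with quantile normalization in the other, per the file headers. The deposited detection p-value of a probe on an array compares its intensity with the negative control beads, as its column name and its range state. The authors also deposited a table of log2 values, which lay within 0.0811 of log2 of the quantile-normalized intensity for every probe and sample, and log2 differences of group means with a p-value per probe from a two-sample test with unequal variances. The series value table was identical to the quantile-normalized report, with a largest difference of 0, so its scale was linear, its values were not centred, and its array medians lay between 178.7 and 179.5. Each report held 16 arrays, of which 1 matched no sample in the labels and was not used here. The authors' quantile normalization was shared with that array. A further deposited count sheet gave the number of probes and genes that the authors called at each time.

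Background correction, normalization and testing started from the intensity without normalization. In R 4.3.3 with limma 3.58.1 (statmod 1.5.0, and data.table in version 1.17.8), the neqc function corrected background with a normexp model fitted through the detection p-values, added an offset of 16, quantile-normalized the 15 arrays and took log2. Of 25697 probes, the 12965 detected at a detection p under 0.01 on at least 3 arrays were kept. A gene was represented by its kept probe with the highest mean over all 15 arrays, which left 9840 genes, 2342 of them with more than 1 kept probe. Gene names came from the report's Entrez identifiers through a RefSeq table of assembly GRCm38.p6, used for names only: 23788 probes matched it, 3935 received a newer symbol, and the file's symbol was kept for the rest, over 18113 symbols on the array. Probe coordinates are printed as the file gives them, and their genome build is not given in the sources used here.

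One linear model with a mean per group was fitted to all 15 arrays with lmFit, and 7 comparisons were tested two-sided with eBayes: each time point against control, and each time point against the one before it. The model had 10 residual degrees of freedom and 2.96 prior degrees of freedom. All adjusted p-values of genes are Benjamini-Hochberg values from limma over the 9840 genes, with a threshold of 0.05. A moderated F-test asked which genes differed among the 5 groups. A fold change is given as a difference of log2 values, with its standard error (SE) from the model. Where a probe was detected on no array of a group, the fold is given as a lower bound. The bright group's mean was set against the dim group's mean of, on each array, the higher of the lowest signal among detected probes and the probe's own signal. No fold is given where that bound was under 1 or where neither group was above background.

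Lists of genes were fixed before the data were examined, for pericyte and mural markers, contractile and myofibroblast genes, extracellular matrix, matrix proteases and inhibitors, TGF-beta and BMP signalling, Wnt and Hedgehog signalling, angiogenic and paracrine factors, cell cycle, p53 and senescence, chemokines and cytokines, interferon response, complement and antigen presentation, hypoxia and glycolysis, oxidative phosphorylation, immediate early genes, heat shock and unfolded protein response, and DNA methylation and chromatin regulators. Marker lists of other cell types covered proximal tubule, distal nephron and collecting duct, injured tubule, podocytes, endothelium, macrophages and monocytes, neutrophils, lymphocytes and erythroid cells. Of these 26 lists, 23 had at least 5 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, with Benjamini-Hochberg adjustment within each comparison. The same test with an estimated correlation, and limma's fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were alternatives. A list score of an array is the mean over the list's measured members of the log2 value minus the control mean.

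Genes were named by a rule written before the data were examined. It took the 10 genes with the largest positive and the 10 with the largest negative log2 difference among those past the threshold and detected on all 3 arrays of the higher group, or all that passed if fewer. Where none passed it took the 5 with the smallest p. From each list described it took up to 4 members with the smallest p, a few of which are not reported here. It also took a fixed set of matrix, pericyte, TGF-beta, DNA methylation and injury genes, given where any of them passed: Acta2, Col1a1, Col3a1, Timp1, Pdgfrb, Pdgfra, Cspg4, Foxd1, Ren1, Acvrl1, Bcor, Tgfb1, Tgfbr1, Dnmt1, Dnmt3b, Havcr1 and Lcn2, as well as Dnmt3a, which was detected on 0 arrays and not tested, and Fn1 and Mki67, for which no probe was matched.

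Arrays have no read depth. Their number, 3 per group, limits the precision, and the signal over background limits what can be measured on each. The background of an array was taken as the median signal of probes with a detection p between 0.45 and 0.55. It separated 8 arrays with a low background from 7 with a high one, and these sets were used, after the data were seen, as a block, as a random block with duplicateCorrelation and for fits within each set. Detection of probes of the Y-linked genes Eif2s3y and Kdm5d was tried as a covariate, also after the data were seen. Alternatives planned before were the authors' quantile values, median scaling in place of quantile normalization, no background correction, no detection filter, detection on at least 8 arrays, every probe as its own feature, a fit to the 2 groups alone, trend and robust options of eBayes, array weights, the replicate number as a block, the authors' criterion of a 2-fold difference with p under 0.05, and leaving out each sample in turn. Python 3.11.15 with matplotlib 3.10.9 drew the plots.

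The model was tested on simulated arrays of 9840 genes with the real spread, for Day 7 against control. It recovered 36% of 100 genes changed 2-fold and 83% of 100 genes changed 4-fold. It made 124 calls, of which 5 were of unchanged genes and 0 had the wrong sign. Each simulated gene was drawn independently of the others. Real genes deviated together, with a mean pairwise correlation of 0.839 among macrophage markers after removal of group means. The simulation thus does not give the error rate of the real calls.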

Results

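RNA of kidney pericytes, the mural and stromal cells around capillaries that carry a Foxd1 lineage label and a Col1a1 reporter, was compared between uninjured kidneys and kidneys after ischemia-reperfusion, a model of acute kidney injury. The series asks which expression changes pericytes show through injury and recovery. There were 3 control samples and 3 samples each at 2, 7, 28 and 56 days, 15 arrays in all. Of the genes on the array, 9840 were detected often enough to be tested. Nothing in the labels says whether the samples of a group are separate animals, so the p-values measure the spread between these samples. The first principal component held 38.7% of the variance and the second 12.2%. Across genes, which are not independent replicates, the correlation of arrays within a group ranged from 0.927 to 0.957 in controls, 0.898 to 0.969 at Day 2, 0.935 to 0.944 at Day 7, 0.959 to 0.976 at Day 28 and 0.963 to 0.973 at Day 56.

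Array background fell into separate ranges. It was between 101.5 and 116.5 intensity units on 8 arrays (all control and Day 2 samples, and Day 7 replicates 1 and 2), which detected 11027 to 12925 probes. On the other 7 arrays (Day 7 replicate 3 and all Day 28 and Day 56 samples) it was between 146.3 and 257.9 units, with 8337 to 11450 probes detected. No background set held both control and Day 28 or Day 56 samples, so for these a fit with the set as a block rests on the Day 7 arrays and no value within a set can be had. Markers of other kidney cells were detected widely: 15 of 17 tested distal nephron markers and 15 of 17 proximal tubule markers were detected on all 15 arrays, against 3 of 16 pericyte markers.

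**Figure D1:**
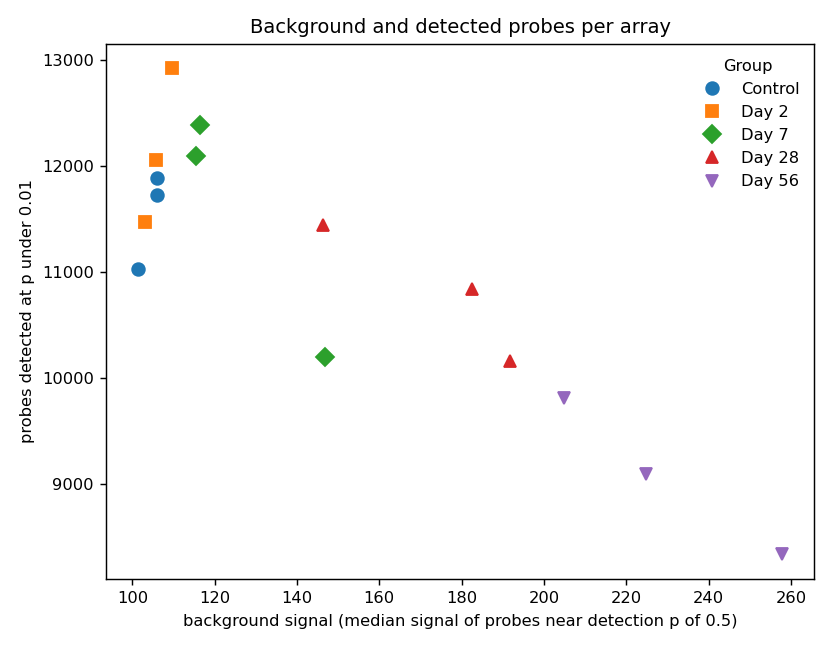
Background signal of each array (intensity units, horizontal) against the number of probes detected at a detection p under 0.01 (vertical), 1 point per array, coloured by group. The 8 arrays with a background of at most 116.5 hold all control and Day 2 samples, and the 7 with at least 146.3 hold all Day 28 and Day 56 samples.

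Day 2 against control asks what the early injury response is. Macrophage and monocyte markers were higher as a group: all 22 measured members had positive log2 differences, with a median of 3.49, or 2.99 with probes not detected in controls set at their bound (camera adjusted p 5.17e-21; adjusted p = 0.368 with an estimated correlation). Cell cycle genes were also higher together, with positive differences in 27 of 27 members and a median of 1.12 (camera adjusted p 5.18e-18; adjusted p = 0.368 with an estimated correlation). Complement and antigen presentation genes were higher, with a median of 0.83 and 13 of 16 members positive, and so were chemokines and cytokines, with a median of 0.46 (0.27 with bounds). Proximal tubule markers were lower, with 17 of 17 members negative and a median of -0.40. These last 3 lists had camera adjusted p of 0.000187, 0.00512 and 0.000449, and each had adjusted p = 0.833 with an estimated correlation. With detection of probes of the Y-linked genes Eif2s3y and Kdm5d as a covariate, called the Y-linked covariate below, 3 more lists passed: distal nephron (median -0.86, adjusted p 0.00148), oxidative phosphorylation (-0.18, 0.00346) and interferon response (0.45, 0.0107).

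The macrophage markers with the smallest p at Day 2 were Adgre1, the F4/80 antigen, at least 16.9-fold brighter than in controls (log2 differences of 3.68 and 1.83 by other probes); Tyrobp, a signalling adaptor of myeloid receptors, at least 8.57-fold brighter; Fcer1g, the shared Fc receptor chain, with a log2 difference of 4.14; and Laptm5, a lysosomal protein of blood cells, with 3.49. In the cell cycle list the differences were 1.08 for Rrm1, a subunit of ribonucleotide reductase, 1.01 for Mcm7 and 1.72 for Mcm5, both parts of the replicative helicase, and 1.75 for Uhrf1, which brings maintenance DNA methyltransferase to replicated DNA. The class II antigen presentation genes H2-DMa, H2-Aa, H2-Eb1 and H2-Ab1 had differences of 2.42, 2.01, 1.91 and 1.81. Among cytokines, Tnf was at least 1.70-fold brighter, and the chemokines Ccl7, Cxcl16 and Cxcl9 had 3.13, 0.69 and 1.25. Of proximal tubule markers, Ggt1, the brush border glutamyltransferase, had -1.06, the fatty acid transporter Slc27a2 -0.63, the urate transporter Slc22a12 -0.83 and the androgen-regulated Kap -1.99. None of these genes passed alone: their adjusted p ranged from 0.361 to 0.655. The Y-linked probes were detected on neither Control replicate 1 nor Day 2 replicates 1 and 2. Y-linked signal was thus not balanced between the groups, and its part in the difference of the androgen-regulated Kap was not separated. The proximal tubule list had a median of -0.41 with the Y-linked covariate (camera adjusted p 0.0014).

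The number of genes past the limma threshold at Day 2 was 0, with 967 at an unadjusted p under 0.05 where 492 would be expected by chance. The 5 smallest p belonged to Spn, the leukocyte sialophorin (at least 1.61-fold dimmer than in controls), Heatr1, a ribosome biogenesis factor (log2 difference 0.93 ± 0.17 SE), Slamf9 (3.50 ± 0.65), the paraoxonase Pon3 (1.22 ± 0.23) and Plcg2, a phospholipase of immune receptor signalling (1.13 ± 0.23), each with an adjusted p of 0.361. Without Day 2 replicate 2, whose macrophage score was 0.24 against 4.16 and 4.35 for the others, 508 genes passed. The same count was 0 with the authors' quantile values, median scaling, no background correction, the replicate block and the background block, and 2295 with array weights. Adjusted over the list alone, 18 macrophage, 16 cell cycle and 5 complement genes passed, all higher, against 0 over all genes. The block leaves this comparison unchanged, with a macrophage median of 3.49, since both groups lie in the low-background set. The chemokine call was lost without Control replicate 1 (adjusted p 0.122), Control replicate 2 (0.159) or Day 2 replicate 1 (0.292), and the proximal tubule call without Control replicate 2 (0.164). The number of lists that passed went from 5 to 11 without Control replicate 3, and to 10 without Day 2 replicate 1 or without Day 2 replicate 2.

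Day 7 against control asks which changes accompany the repair and early fibrotic phase. Macrophage genes had the largest differences: lysozyme Lyz2, a myeloid granule enzyme, was 60.7-fold higher, with a log2 signal of 13.77 ± 0.47 (SD, n = 3) against 7.85 ± 0.50, and adjusted p 0.0412. That is a log2 difference of 5.92, and other probes of Lyz2 had 6.68 and 3.34. The fibrillar collagen gene Col3a1 rose 17.1-fold, from 7.60 ± 1.17 to 11.70 ± 0.74 (SD, n = 3; adjusted p 0.0486), or 26.6-fold without Control replicate 3. Egf, the growth factor precursor made in the distal tubule, was 14.1-fold lower, with 9.90 ± 2.01 against 13.72 ± 0.77 (SD, n = 3; adjusted p 0.0458), but 6.99-fold without Day 7 replicate 1 and 28.1-fold without Day 7 replicate 2. In all, 100 genes passed, 66 higher and 34 lower. By the model's log2 difference 97 of them differed by at least 2-fold, with undetected probes at their normalized signal. By their bounds fewer did, such as Ear10 at least 1.13-fold brighter and Spn at least 1.42-fold dimmer than in controls.

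Of 22 macrophage and monocyte markers, 11 rose by the test over all genes and 19 adjusted over the list alone, 22 of 22 differences were positive, and their median was 4.55 (4.19 with bounds). The 10 largest increases of all were mostly of this kind. Gpnmb, a glycoprotein of lipid-loaded macrophages, was at least 52.9-fold brighter (adjusted p 0.0446; 28.3-fold without Day 7 replicate 1, 107-fold without Day 7 replicate 2), and its other probe had a log2 difference of 1.94. The chemokine gene Ccl9 was at least 56.0-fold brighter (adjusted p 0.0499; 86.0-fold without Day 7 replicate 2). Lyz1, whose probe may share signal with its paralog Lyz2, was 48.0-fold brighter, a log2 difference of 5.58, but its other probes had 1.06 and 2.77. Adgre1 was at least 38.9-fold brighter, with 5.14 and 2.05 by other probes. The membrane protein gene Ms4a7 was at least 27.4-fold brighter (3.10 by its other probe), and Ctss, the antigen-processing protease cathepsin S, 38.0-fold. The complement C1q subunit gene C1qc was 35.3-fold brighter, C1qb had a log2 difference of 4.91 ± 0.95 (SE), and Clec7a, the beta-glucan receptor dectin, at least 16.2-fold. Adjusted p for these was 0.0412, except 0.0426 for C1qb. Camera's adjusted p for the list was 1.36e-20, with adjusted p = 0.359 with an estimated correlation. The median was 4.53 with the background set as a block and 4.53 within the low-background arrays.

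The macrophage difference went with higher immune mediators. Chemokines and cytokines were higher as a group (median 1.45, 1.33 with bounds; camera adjusted p 2.21e-08; adjusted p = 0.359 with an estimated correlation; block median 1.05). Tnf was at least 3.56-fold brighter (adjusted p 0.0412) and Cxcl14 at least 2.20-fold (0.0458; 3.41-fold without Day 7 replicate 2). They were the 2 members past the threshold over all genes, against 12 higher and 1 lower adjusted over the list alone. The alarmin gene Il33 was at least 3.18-fold brighter and Ccl5 had a log2 difference of 1.97, with adjusted p of 0.0547 and 0.0945. Complement and antigen presentation genes were higher (median 0.93; camera adjusted p 1.91e-06; adjusted p = 0.359 with an estimated correlation; block median 0.88). H2-DMa, which loads peptides on class II molecules, rose 6.51-fold (adjusted p 0.0458), the 1 member past the threshold against 7 adjusted over the list alone. H2-Aa, the invariant chain gene Cd74 and H2-Ab1 had log2 differences of 2.96, 2.74 and 2.49 (adjusted p 0.0511, 0.0677 and 0.0693).

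Extracellular matrix genes were higher, with 22 of 24 differences positive and a median of 1.53 (camera adjusted p 1.91e-08; adjusted p = 0.359 with an estimated correlation; block median 1.63). Col3a1 was the 1 member past the threshold over all genes, against 9 adjusted over the list alone. The collagen genes Col6a1 and Col1a2 had log2 differences of 2.89 ± 0.64 and 3.49 ± 0.85 (SE; adjusted p 0.0511 and 0.0664), and Col6a2 was at least 3.97-fold brighter (0.0519). Matrix proteases and inhibitors were higher (median 1.02; camera adjusted p 0.00017; adjusted p = 0.359 with an estimated correlation; block median 0.79), with 0 members past the threshold (limma) and 5 adjusted over the list alone. In it Timp1, the metalloprotease inhibitor, had 4.01 ± 0.88 (adjusted p 0.0511), the protease gene Mmp14 had 2.53 (0.0702), Mmp13 was at least 2.28-fold brighter (0.118), and the collagen chaperone gene Serpinh1 had 1.17 (0.0958). TGF-beta and BMP signalling genes were higher by a small median of 0.35 (camera adjusted p 0.0192; adjusted p = 0.431 with an estimated correlation; block median 0.28). In it 0 members passed over all genes and 1 adjusted over the list alone. The ligand gene Tgfb1 was at least 2.02-fold brighter (adjusted p 0.0668), and Tgfbi, Tgfbr1 and Acvr1 had log2 differences of 3.56, 0.70 and 0.43 (0.117, 0.135 and 0.155). That call was lost without Control replicate 1 (adjusted p 0.0734), Control replicate 2 (0.224) or Day 7 replicate 1 (0.0973).

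Distal nephron and collecting duct markers were lower at Day 7, with 17 of 17 differences negative and a median of -1.99. Over all genes 4 members passed, and 16 did adjusted over the list alone (camera adjusted p 1.39e-12; adjusted p = 0.359 with an estimated correlation; median -2.10 with the block). Besides Egf, Aqp3, the collecting duct water channel, had a log2 difference of -2.61 ± 0.55 (SE), with an adjusted p of 0.0458. The remaining genes among the 10 largest decreases were Perm1, a regulator of mitochondrial genes, with -3.06 ± 0.61 (adjusted p 0.0431), the adaptor gene Shd with -2.67 ± 0.49 (0.0412), Atp4a, a proton pump subunit, with -2.54 ± 0.54 (0.0458; -1.85 without Control replicate 1), Tmem52b with -2.38 ± 0.42 (0.0412), the nucleic acid binding Ybx2 with -2.37 ± 0.44 (0.0412; -1.78 without Day 7 replicate 1), and Car15, a carbonic anhydrase, with -2.36 ± 0.42 (0.0412). The kallikrein genes Klk1b8 (-2.42 ± 0.47, adjusted p 0.0431) and Klk1b27 (-2.36 ± 0.42, 0.0412; -1.75 by its other probe) complete them, and as close paralogs their probes may share signal.

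Oxidative phosphorylation genes were lower by a median of -0.41, with 22 of 24 differences negative (camera adjusted p 1.47e-06; adjusted p = 0.359 with an estimated correlation; median -0.35 with the block). In that list 0 members passed over all genes and 8 adjusted over the list alone. Ppargc1a, the coactivator that drives mitochondrial biogenesis, had -1.08, and Idh3a, Cyc1 and Uqcrc1 had -0.94, -0.77 and -0.71, with adjusted p from 0.0846 to 0.111. Genes of p53 and senescence were higher (median 0.55; camera adjusted p 0.0036; adjusted p = 0.359 with an estimated correlation; block median 0.43), with 0 past the threshold on either adjustment. Among them Bax, Pmaip1, Gdf15 and Mdm2, all p53 targets, had differences of 0.91, 1.09, 1.91 and 0.55 (adjusted p 0.101 to 0.212). Injured tubule markers had a median of 0.72 with 10 of 11 positive, and 3 passed adjusted over the list alone against 0 over all genes (camera adjusted p 0.00236; adjusted p = 0.359 with an estimated correlation). That call was lost with the block (median 0.32, adjusted p 0.101), without Control replicate 2 (0.0727) and without Day 7 replicate 3 (0.101). Within it Lcn2 had 2.69, Krt20 2.87, Havcr1, the kidney injury molecule, 3.92 ± 1.27 (SE) and Sox9 1.13, with adjusted p of 0.114, 0.117, 0.127 and 0.310.

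Pericyte and contractile genes did not pass camera as groups at Day 7. Pericyte and mural markers had a median of -0.31 (camera adjusted p 0.463), with 2 higher and 1 lower adjusted over the list alone, and fry for change in either direction gave an adjusted p of 0.00848, but so tested 13 of the 23 lists had one under 0.05. There Nt5e had 1.16, Thy1 2.52, Notch3, the mural cell receptor, -1.46 and Foxd1, the stromal lineage factor, -1.06 ± 0.37 (SE), with adjusted p of 0.0683, 0.0925, 0.0945 and 0.143. Contractile and myofibroblast genes had a median of -0.33 (camera adjusted p 0.290), with 1 lower adjusted over the list alone. Their median was -0.41 with the block (adjusted p 0.0840) and within the low-background arrays, where they passed (0.0337). Smooth muscle myosin Myh11 had -2.48, Vim 1.67, Tagln -0.90 and Acta2, the smooth muscle actin that marks myofibroblasts, -1.32 ± 0.54 (SE), and their adjusted p lay between 0.0770 and 0.208. Other fixed genes that did not pass were Col1a1 (3.66 ± 1.16, adjusted p 0.122), Pdgfra (1.72, 0.341), Pdgfrb (-0.28, 0.802), Cspg4 (-0.35, 0.493), Ren1 (-0.48, 0.641) and Acvrl1 (-0.33, 0.605). The chromatin genes Bcor (0.11), Dnmt1 (0.48, adjusted p 0.398) and Dnmt3b (-0.10, 0.879) did not pass either. Of the 15 arrays, Acvrl1 was detected on 4, Pdgfrb on 6, Foxd1 and Ren1 on 8, Pdgfra on 9, Col1a1 on 10 and Cspg4 on 11. Differences of probes so often at background do not show that these genes were unchanged.

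The other lists did not pass camera at Day 7. Their medians and adjusted p were 0.31 and 0.0571 for cell cycle, 0.25 and 0.125 for interferon response, -0.24 and 0.0542 for hypoxia and glycolysis, 0.32 and 0.156 for immediate early genes, and 0.23 and 0.0602 for heat shock and unfolded protein response. For DNA methylation and chromatin regulators they were -0.02 (with a mean of 0.00572, opposite in sign) and 0.857, for Wnt and Hedgehog signalling -0.11 and 0.391, and for angiogenic and paracrine factors -0.25 and 0.769. Among other cell types they were -0.19 and 0.463 for proximal tubule, -0.43 and 0.338 for podocytes and -0.58 and 0.145 for endothelium. Some of these passed in other fits: endothelium was lower by a median of -0.92 with the block (adjusted p 0.000546), within the low-background arrays (0.000347) and with the Y-linked covariate (median -0.93, 0.00187). Hypoxia and glycolysis passed with the block (-0.44, 0.0233), within the low-background arrays (0.0310) and with the covariate (-0.22, 0.0478). Cell cycle passed with the block (0.44, 0.0233) and within the low-background arrays (0.0244), and heat shock with the covariate (0.22, 0.0348). In 2 of these lists a member passed over all genes, and these members are named here after their values were seen: the Wnt inhibitor gene Sfrp1 was lower by limma (-2.27) and Igf1, a growth factor gene, was higher (1.61). Neutrophil and lymphocyte markers with 4 measured members each, and erythroid markers with 3, were too few to test. Fry passed 3 lists at Day 7: macrophage (adjusted p 0.0264), distal nephron (0.0264) and hypoxia and glycolysis (0.0362).

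The smallest limma adjusted p at Day 7 was 0.0362, so the 100 calls lay close to the threshold, and 1840 genes had an unadjusted p under 0.05. The count was 0 without Control replicate 1, 159 without Control replicate 2, 0 without Control replicate 3, 1 without Day 7 replicate 1, 330 without Day 7 replicate 2 and 3 without Day 7 replicate 3. It was 3 with the background set as a block and 0 within the low-background arrays, which hold 2 of the Day 7 samples. It was also 0 with the Y-linked covariate, whose probes were detected on all Day 7 arrays and not on Control replicate 1. With the block and within the low-background arrays, all 100 genes kept their direction and an unadjusted p under 0.05. Both rest on the same arrays for this comparison. The genes were picked with these arrays among the samples, so this is nearly fixed in advance and is not separate support.

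**Figure D2:**
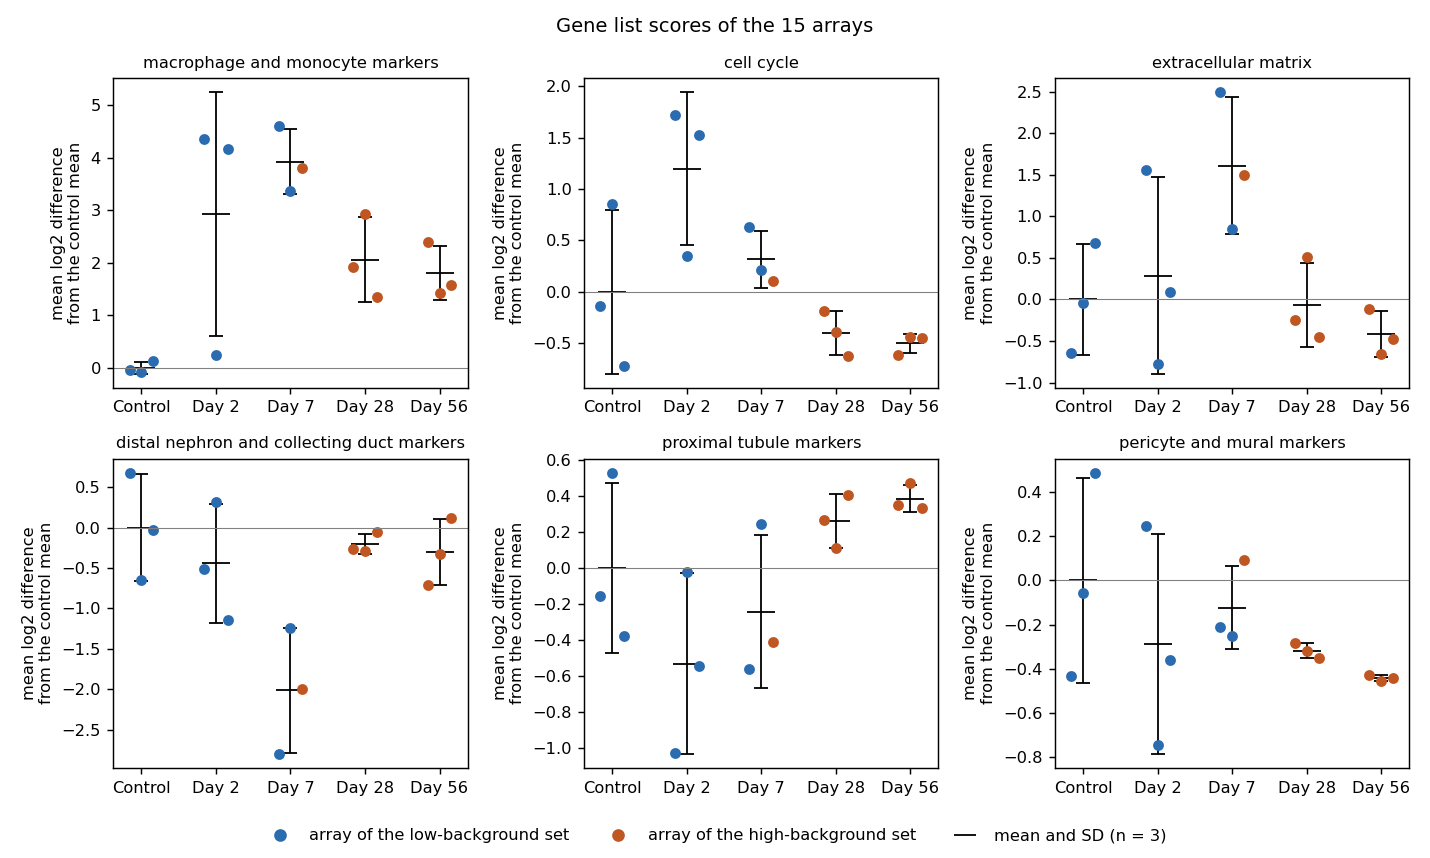
Scores of 6 gene lists per array (mean log2 difference of the list's measured members from the control mean, vertical) by group, with points coloured by background set and the mean and SD of 3 arrays. The macrophage score was 3.92 ± 0.63 at Day 7 and 1.80 ± 0.52 at Day 56, and the distal nephron score was -2.01 ± 0.78 at Day 7.

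**Figure D3:**
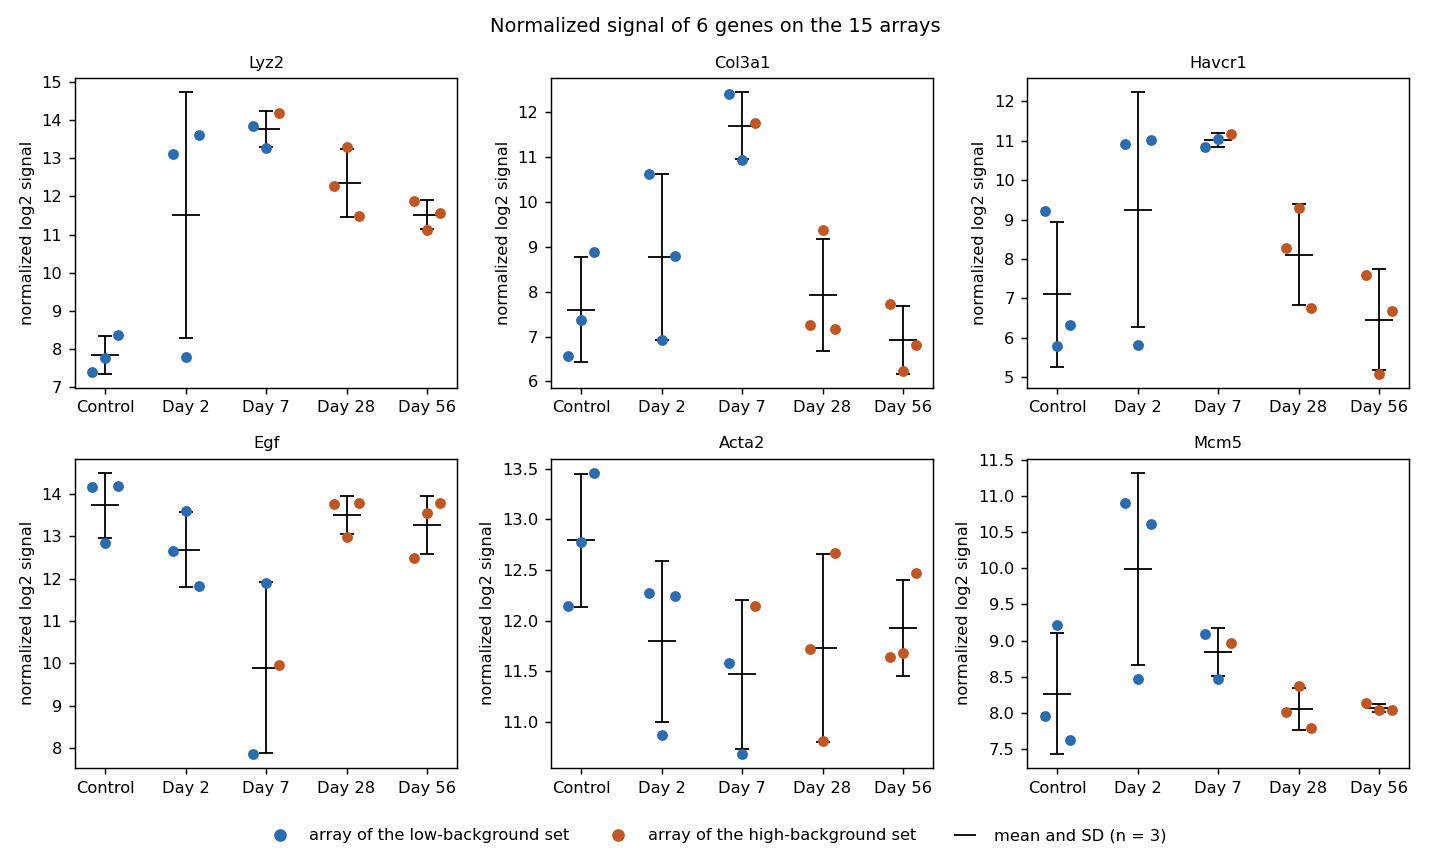
Normalized log2 signal of Lyz2, Col3a1, Havcr1, Egf, Acta2 and Mcm5 on each of the 15 arrays by group, with the mean and SD of 3 arrays. Lyz2 reached 13.77 ± 0.47 at Day 7 against 7.85 ± 0.50 in controls.

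Day 28 against control asks what lasts after the repair phase. Macrophage and monocyte markers were higher in all 22 members, with a median log2 difference of 2.24 (1.74 with bounds), and complement and antigen presentation genes were higher by a median of 0.63. Camera's adjusted p was 2.91e-13 and 1.12e-05, each with adjusted p = 0.886 with an estimated correlation. Contractile and myofibroblast genes were lower, with 10 of 12 negative and a median of -0.60, and cell cycle genes were lower by a median of -0.36 (-0.21 with bounds). Their camera adjusted p was 0.0113 and 0.0230, each with adjusted p = 0.963 with an estimated correlation. Proximal tubule markers had a median of 0.32 and injured tubule markers one of 0.37, with 11 of 11 members positive. Camera gave 0.0488 for both, and with an estimated correlation the adjusted p of all 6 lists ranged from 0.886 to 0.963.

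In the macrophage list Lyz2 had a log2 difference of 4.50, Lyz1 4.13 and Ctss 3.13, and Adgre1 was at least 7.47-fold brighter. Other probes had 4.00 and 0.91 for Lyz2, 0.93 and 2.69 for Lyz1, and 2.94 and 0.55 for Adgre1. The complement factor B gene Cfb had 1.20 (adjusted p 0.185), and the class II genes H2-Aa, Cd74 and H2-Eb1 had 2.57, 2.47 and 2.22. The contractile genes Tagln, Smtn and Myh11 had -0.97, -0.58 and -1.47, and Acta2 had -1.06 (adjusted p 0.678). With the block the medians were 2.36 for macrophage (adjusted p 0.000105), 0.71 for complement (0.0653), -0.98 for contractile (0.000971), -0.15 for cell cycle (0.639), 0.71 for proximal tubule (0.0237), and -0.56 for injured tubule (0.0402), a turn in direction. The block passed 10 lists in all, and among them 6 did not pass without it: endothelium (-1.41, adjusted p 0.000105, against a median of 0.11), chemokines (-0.77, 0.000543, against 0.22), heat shock (-0.65, 4.44e-05), immediate early (-0.74, 0.00637, against 0.14), interferon response (-1.16, 0.00595) and pericyte markers (-0.75, 0.0118). These block values carry the deviation of 1 array, Day 7 replicate 3, from the other Day 7 arrays onto all Day 28 samples. With the Y-linked covariate neither tubule list passed (0.0584 for both). Adjusted over the list alone, 9 macrophage and 5 complement genes passed and 0 contractile genes, against 0 over all genes.

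By limma 0 genes passed at Day 28, 754 had an unadjusted p under 0.05, and the count was 0 with the authors' quantile values, 1 in a fit to the 2 groups alone and 716 with array weights. The 5 smallest p were for Hrob, a factor of homologous recombination (log2 signal 4.90 against 5.94, adjusted p 0.0825), Spn (at least 1.22-fold dimmer than in controls, 0.0825), Atat1, the tubulin acetyltransferase (at least 1.04-fold dimmer, 0.111), Rasef (at least 1.22-fold dimmer, 0.147) and Mfsd5 (log2 difference 0.90 ± 0.17 SE, 0.157). Several list calls ended with 1 sample left out. For contractile genes the call was lost without Control replicate 3 (median -0.36, adjusted p 0.227) or Day 28 replicate 2 (-0.39, 0.117). For cell cycle the median was 0.15, opposite in sign, without Control replicate 2 (adjusted p 0.850), and the call was lost without Day 28 replicate 3 (0.145). For proximal tubule it was lost without Control replicate 1 (0.276), Control replicate 3 (0.459), Day 28 replicate 1 (0.0553) or Day 28 replicate 3 (0.244). For injured tubule it was lost without Control replicate 2 (0.663), Day 28 replicate 1 (0.118) or Day 28 replicate 2 (0.131). The number of lists that passed went from 6 to 10 without Control replicate 3 and to 4 without Day 28 replicate 1, 2 or 3 in turn.

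Day 56 against control asks what remains latest. Here 20 genes passed, 7 higher and 13 lower. By the model's log2 difference 18 of them differed by at least 2-fold, with undetected probes at their normalized signal. Of the 13 lower genes 12 were detected on no Day 56 array, and the highest bound among these was 1.39-fold. With median scaling 0 higher and 1 lower gene passed, and without the detection filter 58 higher and 50 lower. Cfb, a protease of the alternative complement pathway, rose 2.66-fold, with a log2 signal of 11.30 ± 0.15 against 9.89 ± 0.34 (SD, n = 3; adjusted p 0.0463). The other increases were of Slc43a2, a neutral amino acid transporter (3.07-fold, adjusted p 0.0470), the deubiquitinase gene Vcpip1 (2.82-fold, 0.0391), the expressed sequence AA388235 (at least 2.28-fold, 0.0470), the zinc finger gene Zbtb14 (2.28-fold, 0.0236) and Mfsd14b (2.15-fold, 0.0463). Another probe of Slc43a2 had a log2 difference of 0.60 against 1.62. The seventh, Fam180a, was detected on 2 Day 56 arrays and is named after its values were seen (at least 2.09-fold).

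The 10 largest decreases at Day 56 were all of genes detected on no Day 56 array, so a fold is given only as a lower bound, and log2 signals where there is no bound. For Rasef, a small GTPase, they were 4.88 ± 0.09 at Day 56 against 6.42 ± 0.13 in controls (SD, n = 3; adjusted p 0.00955). Apc, the Wnt pathway scaffold, had 5.24 ± 0.28 against 6.74 ± 0.18 (SD; adjusted p 0.0146), and Spn 5.02 against 6.42 (0.0146). Ptges3l was at least 1.39-fold dimmer than in controls (adjusted p 0.0146) and Rhbdd3 at least 1.16-fold (0.0470). Atat1 had 4.94 against 6.19 (0.0236) and Lmbr1 4.94 against 6.32 (0.0470). The adjusted p was 0.0463 for 5830435K17Rik (5.21 against 6.57), Cacna2d1, a calcium channel subunit (5.05 against 6.26), and Fam204a (5.07 against 6.23). Of all 13 lower genes, 12 were detected on no Day 56 array.

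Macrophage markers were still higher at Day 56, with 22 of 22 members positive and a median of 1.88 (1.46 with bounds; camera adjusted p 3.37e-09; 5 genes adjusted over the list alone against 0). This list and the 4 that follow each had adjusted p = 0.900 with an estimated correlation. Lyz1 had a log2 difference of 3.48, Lyz2 3.67 and Ctss 3.06, and Adgre1 was at least 7.21-fold brighter. Other probes had 0.21 and 2.32 for Lyz1, 3.07 and 0.63 for Lyz2, and 2.97 and 0.73 for Adgre1. Complement and antigen presentation genes had a median of 0.87 with 11 of 16 positive (camera adjusted p 0.000111; 5 adjusted over the list alone against 1, Cfb, over all genes), and H2-Aa, Cd74 and H2-Eb1 had 2.84, 2.57 and 2.37. Podocyte markers had a median of 0.85 and 7 of 7 positive (camera adjusted p 0.00304). Of these, Enpep, an aminopeptidase, had 1.01, Ptpro, a podocyte phosphatase, 0.85 and Podxl, the podocalyxin gene, 1.01. Proximal tubule markers had a median of 0.41 (camera adjusted p 0.00388), and Hnf4a and Gatm had 0.70 and 1.19. With median scaling the proximal tubule median was -0.05, but the median of all genes was then -0.40, so the list still lay above it. Cell cycle genes had a median of -0.43, which was 0 with probes at their bound (camera adjusted p 0.0322), and Bub1b, Top2a, Plk1 and Mcm7 were detected on no Day 56 array.

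With the background set as a block the medians at Day 56 were 2.22 for macrophage (adjusted p 0.000261), 0.57 for complement (0.0437), 0.79 for podocytes (0.0476), 0.83 for proximal tubule (0.0038) and -0.24 for cell cycle (0.501). The block passed 12 lists in all, and among them 8 did not pass without it: endothelium (-1.90, adjusted p 6.61e-07), chemokines (-1.51, 0.000261), immediate early (-1.30, 0.000261), heat shock (-0.56, 0.000261), contractile (-0.86, 0.0038), interferon response (-1.19, 0.0149), pericyte markers (-0.32, 0.0229) and injured tubule (-0.53, 0.0437, against a median of 0.39). These block values rest on Day 7 replicate 3, the 1 Day 7 array with a high background, against the other Day 7 arrays. Its endothelial score was 0.53 against -1.14 and -0.75, and its chemokine score 2.55 against 1.51 and 0.77. The block carries that deviation of 1 array onto all Day 56 samples. With the Y-linked covariate endothelium passed too (-0.72, 0.00464). By limma the 20 calls were 1 with the background block, 9 with the Y-linked covariate and 0 with the authors' quantile values or without background correction. They were 12 without Control replicate 1, 2 without Control replicate 2, 2 without Control replicate 3, 1 without Day 56 replicate 2 and 2 without Day 56 replicate 3. Under the proximal tubule list the call was lost without Control replicate 3 (0.104). The cell cycle call was lost without Day 56 replicate 1 (0.167) and turned without Control replicate 2 (median -0.0327, adjusted p 0.952, tested as higher). The number of lists that passed went from 5 to 9 without Control replicate 1 and to 8 without Control replicate 3.

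Day 7 against Day 2 asks how the repair phase differs from early injury. Extracellular matrix genes were higher at Day 7 (median log2 difference 1.29; camera adjusted p 3.04e-10), as were matrix proteases and inhibitors (0.95; 1.37e-05), each with adjusted p = 0.367 with an estimated correlation. Distal nephron markers were lower (-1.36; 8.33e-14; adjusted p = 0.332 with an estimated correlation) and cell cycle genes were lower in 27 of 27 members (-0.91; 1.96e-10; adjusted p = 0.367 with an estimated correlation). The collagen genes Col6a2, Col6a1, Col1a2 and Col3a1 had log2 differences of 2.55, 2.74, 2.88 and 2.92 (adjusted p 0.393 for Col3a1). Mmp2, the gelatinase, had 2.40, Timp1 1.72, Mmp14 1.27 and Serpinh1 0.97. In the distal nephron list Slc4a9, a bicarbonate exchanger, had -2.76, Slc12a3, the thiazide-sensitive transporter, -1.97 and Tmem52b -1.95. Of cell cycle genes, Bub1b, a spindle checkpoint kinase, had -1.33, and the replication genes Cdc45, Rrm1 and Mcm2 had -1.07, -0.83 and -0.81.

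A further 10 lists passed camera between Day 7 and Day 2, and 14 in all. Higher were chemokines (median 1.04; adjusted p 3.66e-06), macrophage markers (1.08; 0.000159), p53 and senescence (0.45; 0.000499), immediate early genes (0.49; 0.00312), proximal tubule (0.25; 0.00515), TGF-beta and BMP signalling (0.10; 0.0137), complement (0.42; 0.0140) and injured tubule (0.63; 0.0230). Lower were oxidative phosphorylation (-0.31; 1.42e-05) and hypoxia and glycolysis (-0.21; 0.0140). With an estimated correlation these 10 had adjusted p = 0.367 for p53, 0.332 for hypoxia, 0.499 for TGF-beta, chemokines and oxidative phosphorylation, and 0.548 for the other 5. Adjusted over the list alone, 4 matrix and 12 distal nephron genes passed, against 0 over all genes. With the block the medians were 1.36 for matrix, 0.68 for proteases, -0.81 for cell cycle, -1.62 for distal nephron, 0.29 for p53, 0.51 for chemokines, 0.12 for TGF-beta and 1.09 for macrophage, and the calls ended for complement (adjusted p 0.0645), immediate early (0.315) and injured tubule (0.696). Endothelium passed with the block (-0.80, adjusted p 0.000501), within the low-background arrays (0.000573) and with the Y-linked covariate (-0.98, 9.32e-06). The covariate ended the calls of macrophage (0.146), complement (0.0634), TGF-beta (0.0856), hypoxia (0.0856), immediate early (0.291) and injured tubule (0.115).

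By limma 0 genes passed between Day 7 and Day 2, with 817 at an unadjusted p under 0.05, 3 with the background block and 0 with the authors' quantile values. The smallest p belonged to Klk1b5 (-1.78 ± 0.31), Plcg2 (-1.30), LOC100044702 (2.35), Klk1 (-1.23) and Klk1b4 (-2.09), each with an adjusted p of 0.218, and the kallikrein probes may share signal. The gene count was 1 without Day 2 replicate 3, 1 without Day 7 replicate 1, 3 without Day 7 replicate 2 and 3 without Day 7 replicate 3. Without Day 2 replicate 2 the number of lists went from 14 to 7. The medians then were -0.0168 for complement (adjusted p 0.463) and -0.19 for macrophage markers (0.0992), opposite in sign. Also lost without it were TGF-beta (0.322), p53 (0.0525), chemokines (0.0992), hypoxia (0.170), oxidative phosphorylation (0.108), immediate early (0.377) and injured tubule (0.784). Proximal tubule was lost without Day 2 replicate 1 (0.202) or Day 7 replicate 2 (0.312), and TGF-beta (0.128) and hypoxia (0.115) without Day 7 replicate 1. Complement (0.0645), immediate early (0.315) and injured tubule (0.696) were lost without Day 7 replicate 3.

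Day 28 against Day 7 asks what resolves. Extracellular matrix genes were lower at Day 28 (median -1.47; camera adjusted p 2.50e-10; 9 lower adjusted over the list alone), macrophage markers were lower (-2.12; 3.31e-08), and distal nephron markers were higher (1.66; 2.68e-13; 14 adjusted over the list alone). For matrix and distal nephron adjusted p = 0.353 with an estimated correlation, and for macrophage 0.409. Col3a1 had a log2 difference of -3.77 and Col6a1 -2.65, while Lum, the lumican proteoglycan gene, was at least 4.86-fold dimmer and Col6a2 at least 3.36-fold. Egf had 3.60, Tmem52b 2.39 and Kcnj1, the potassium channel of the thick limb and collecting duct, 2.29. C1qa, C1qc and C1qb had -2.51, -2.52 and -2.55, and Adgre1 -2.38 (-2.20 and -1.50 by other probes). Chemokines and cytokines were lower (-1.37; 1.71e-07; adjusted p = 0.396 with an estimated correlation), with Cxcl2 at -3.79, Il33 at -1.62, and Tnf at least 3.01-fold and Cxcl14 at least 1.87-fold dimmer. Oxidative phosphorylation genes were higher (0.43; 5.17e-06; adjusted p = 0.409 with an estimated correlation), with 0.69 for Sdhb, 0.60 for Atp5a1, 0.57 for Cs and 0.41 for Cox6c, all enzymes or subunits of mitochondrial respiration.

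The other lists past camera between Day 28 and Day 7 were matrix proteases (median -1.23; adjusted p 5.17e-06), cell cycle (-0.65; 1.12e-05), p53 and senescence (-0.47; 0.000425), heat shock and unfolded protein response (-0.27; 0.000625), proximal tubule (0.36; 0.00656), hypoxia and glycolysis (0.28; 0.0186) and endothelium (0.62; 0.0213). With an estimated correlation these had adjusted p = 0.353 for proteases, p53, hypoxia and heat shock, 0.445 for cell cycle, 0.569 for proximal tubule and 0.694 for endothelium. With the block the medians were -1.32 for matrix, -1.96 for macrophage, 1.78 for distal nephron, -2.20 for chemokines, -1.43 for proteases, -0.64 for cell cycle, -0.69 for p53, -0.89 for heat shock, 0.52 for oxidative phosphorylation and 0.51 for proximal tubule. Within the high-background arrays, with 1 Day 7 sample, the matrix median was -1.32. The block ended the hypoxia call (0.16; adjusted p 0.234) and turned that of endothelium (-0.57; 0.163). Lists that passed only with the block were injured tubule (-1.74, adjusted p 0.000379), interferon response (adjusted p 0.00131), immediate early (-0.68, 0.00290) and contractile (-0.43, 0.0458). In this comparison the block in effect sets Day 28 against Day 7 replicate 3, so the size of these differences rests on 1 Day 7 sample. Complement had a median of -0.62 within the high-background arrays, again with 1 Day 7 sample. Wnt and Hedgehog signalling passed with the Y-linked covariate alone (0.25, 0.0428).

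By limma 0 genes passed between Day 28 and Day 7, with 1386 at an unadjusted p under 0.05, 0 with the authors' quantile values and 7 with the background block. The high-background arrays hold 1 Day 7 sample, without a spread of its own. A count for this comparison within them is thus not read as a number of changed genes. The smallest p belonged to Igf1, at least 3.73-fold brighter at Day 7, Klk1b5 (1.93), Klk1 (1.37), the calcium-binding S100g (2.24) and the potassium channel subunit gene Kcne1 (1.69), each with an adjusted p of 0.106. The gene count was 1 without Day 7 replicate 1, 18 without Day 7 replicate 2 and 1 without Day 7 replicate 3. Hypoxia was lost without Day 7 replicate 1 (0.0652), proximal tubule without Day 7 replicate 1 (0.0664) or replicate 3 (0.0533), and heat shock without Day 7 replicate 3 (0.154). Endothelium was lost without Day 7 replicate 1 (0.328) or replicate 2 (0.224), and without Day 28 replicate 1 (0.0652) or replicate 2 (0.296).

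Day 56 against Day 28 asks whether the late state still moves. Podocyte markers were higher at Day 56 (median 1.08; camera adjusted p 1.04e-09; 3 adjusted over the list alone; adjusted p = 0.0517 with an estimated correlation; the same median with the block). Cdkn1c, a cell cycle inhibitor of mature podocytes, had a log2 difference of 1.82 and Ptpro 1.17. Endothelial markers were lower (median -0.51; camera adjusted p 0.0122; adjusted p = 0.997 with an estimated correlation; -0.51 with the block). Among them Plvap, the fenestral diaphragm protein, had -1.61, Egfl7 -0.82, Tek, the angiopoietin receptor, -0.77 and Ramp2 -0.68. The endothelial call was lost without Day 28 replicate 1 (0.116), Day 28 replicate 2 (0.471) or Day 56 replicate 2 (0.521), which takes the number of lists from 2 to 1. By limma 0 genes passed, with 331 at an unadjusted p under 0.05, 0 with the authors' quantile values, 4 without the detection filter and 3 with array weights. The 5 smallest p were for the mannosidase gene Man2a2, at least 1.73-fold brighter at Day 56 (adjusted p 0.185), AA388235, at least 1.93-fold, Fdxacb1 (log2 signal 5.16 against 6.37), Fam180a, at least 1.77-fold (0.377), and Mypop (4.98 against 6.22, 0.442). Immediate early genes passed with the block, within the high-background arrays (-0.41, adjusted p 0.000112) and with the Y-linked covariate (-0.67, 0.000822). The gene count was 1 without Day 56 replicate 1 and 1 without Day 56 replicate 2.

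Across all 5 groups, the F-test called 12 genes, with 1943 at an unadjusted p under 0.05. Rasef had the smallest adjusted p (0.0247), followed by Atat1, Spn, Hrob, Zbtb14, Apc, AA388235, Ptges3l, Kank2, LOC100044702 and Igf1 (0.0383 each) and the helicase gene Pif1 (0.0421), named after their values were seen where not named above. Igf1 signal was 6.42 in controls, 6.80 at Day 2, 8.03 at Day 7, 5.83 at Day 28 and 5.51 at Day 56. Most of the 12 genes were dim on the late, high-background arrays. All but Zbtb14 (8.09) and AA388235 (7.08) had Day 56 means from 4.71 (LOC100044702) to 5.79 (Ptges3l). With detection required on at least 8 arrays the F count was 0. The count of 12 was 0 without Control replicate 1, 3 without Control replicate 2, 0 without Control replicate 3, 2 without Day 2 replicate 1, 784 without Day 2 replicate 2 and 0 without Day 2 replicate 3. It was 26 without Day 7 replicate 2 and 30 without Day 7 replicate 3. It was 1, 0 and 1 without Day 28 replicates 1, 2 and 3 in turn, and 0 without Day 56 replicate 2 or without Day 56 replicate 3.

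Changes at different times share the same controls, which makes them alike. At an unadjusted p under 0.01 there were 742 genes at Day 7, of which 131 were shared in the same direction with the 249 at Day 2, 62 with the 194 at Day 28 and 82 with the 468 at Day 56. Simulated groups with no change and shared controls gave 15.9, 15.2 and 15.8, and independent lists of these lengths 9.81, 7.28 and 17.3. Across genes, the differences at Day 7 had correlations of 0.765 with those at Day 2, 0.585 with Day 28 and 0.445 with Day 56. The simulated groups gave 0.4999 for Day 2, 0.4999 for Day 28 and 0.501 for Day 56. Only the Day 56 correlation lay below its simulated value. The covariances, which are not scaled by the spread of the differences, were 0.305, 0.178 and 0.155 for Day 2, Day 28 and Day 56. The simulated covariances were 0.0617, 0.0616 and 0.0617, so each real one lay above. Whether Day 56 lay below or above what shared controls alone give thus depends on the measure. At the adjusted threshold Day 7 and Day 56 shared 2 genes, Rasef and Spn, where the simulated groups gave 0 and independent lists 0.0919. The simulated values leave out the effects and the independent ones leave out the shared controls, so an excess over either is not read as a shared effect. The 3 controls cannot be divided into 2 parts of at least 2 samples, so the overlap was not measured with separate controls.

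The authors' deposited count sheet gives 4 probes (3 genes) for Day 2 against control, 224 (178) for Day 7, 34 (25) for Day 28 and 38 (28) for Day 56. Recounted from their probe table, 4, 224, 33 and 38 probes met a 2-fold difference and p under 0.05. Of these, 183 were higher and 41 lower at Day 7, and 36 higher and 2 lower at Day 56. Probe positions are as the file gives them, with a build that is not given in the sources used here: Gpnmb on chromosome 6 at 49006694 to 49006743, Egf on chromosome 3 at 129380827 to 129380876, Lyz2 on chromosome 10 at 116714443 to 116714492 and Rasef on chromosome 4 at 73361347 to 73361396.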

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

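The tests of 3 patterns below were chosen after the result was seen; the counts of other splits were planned before.

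Several gene lists differed between adjacent time points by camera's test of the difference itself, which is what singles them out here. From Day 2 to Day 7 the median log2 difference was 1.29 for extracellular matrix, 0.95 for matrix proteases and inhibitors, 0.10 for TGF-beta and BMP signalling, -0.91 for cell cycle, 0.45 for p53 and senescence, 1.04 for chemokines and cytokines and 0.42 for complement and antigen presentation. For the same times it was -0.21 for hypoxia and glycolysis, -0.31 for oxidative phosphorylation, 0.49 for immediate early genes, 0.25 for proximal tubule, -1.36 for distal nephron, 0.63 for injured tubule and 1.08 for macrophage markers. From Day 7 to Day 28 it was -1.47 for extracellular matrix, -1.23 for matrix proteases, -0.65 for cell cycle, -0.47 for p53 and senescence, -1.37 for chemokines, 0.28 for hypoxia and glycolysis and 0.43 for oxidative phosphorylation. It was -0.27 for heat shock and unfolded protein response, 0.36 for proximal tubule, 1.66 for distal nephron, 0.62 for endothelium and -2.12 for macrophage markers. From Day 28 to Day 56 it was 1.08 for podocyte and -0.51 for endothelial markers. None of the 28 passed with an estimated correlation, where adjusted p ranged from 0.332 to 0.548, 0.353 to 0.694 and 0.0517 to 0.997 over the 3 comparisons. Of the 14 lists from Day 2 to Day 7, 9 were lost without Day 2 replicate 2, the array that sits with the controls. The medians without it were -0.0168 for complement and -0.19 for macrophage markers, opposite in sign.

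Macrophage markers were higher and distal nephron markers lower at Day 7, and array background as the whole cause is argued against, since within the low-background arrays the macrophage median was 4.53 with scores of 3.36 and 4.60 on the Day 7 arrays, against a control SD of 0.114, and the distal nephron median was -2.10. Dilution of tubule RNA by other RNA would lower proximal tubule markers alike, but they had a median of -0.192 (SD over members 0.401) against -1.99. Distal minus proximal scores of the Day 7 arrays (-2.24 to -1.49) lay outside the controls (-1.18 to 0.83), the nearest by less than their SD of 1.05. These values argue against dilution as the whole cause of the distal difference, with a limit. Proximal markers were brighter in controls, with a median log2 signal of 12.48 against 10.47 for distal ones. Whether probes that bright show a fall in full was not tested. RNA of macrophages among the isolated cells may account for the macrophage part, with Lyz2 at a log2 signal of 13.77 and 8 of 22 markers detected on all 15 arrays, and the sort that might have removed such cells is not given in the sources used here. The mean pairwise correlation of the markers after removal of group means, 0.839, leaves it open, because 13 of 16 lists that mark no cell type also exceeded the 95th percentile of random lists (0.0676), up to 0.711. A response of the pericytes or other kidney cells to injury, which the design names, stays open and untested.

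Day 2 replicate 2 sits with the controls. A swap with a control is argued against, because the highest macrophage score of a control was 0.130 while the other Day 2 samples had 4.16 and 4.35. A single wrong label, or a kidney with little injury, could each give its score of 0.239. Its Adgre1 signal of 7.22 lay above the controls (5.59 to 5.79) and 10 of 22 macrophage markers were higher than in every control, as were 23.5% of all genes, which leans to a little injury, but 8 were highest in Control replicate 3 among the same 4 samples, so a wrong label stays open. Its correlation across genes with Control replicate 1, 0.982, was the highest of any pair of arrays. On both of these arrays Xist was detected and the probes of Eif2s3y and Kdm5d were not.

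For the 20 genes past the threshold at Day 56, the array background may contribute: in 14 of them Day 7 replicate 3, the high-background array of its group, deviated from the other Day 7 arrays in the Day 56 direction. With the set as a block 1 was called, all 20 kept their direction, the median signed log2 difference went from 1.39 ± 0.224 (SD over genes) to 1.18 ± 0.598, and the calls ended as the median SE went from 0.201 to 0.360. Background correction of dim probes is open too: without it 0 of the genes turned and 0 were called (adjusted p 0.0958 to 0.185), with a median of 0.517 ± 0.199, and 12 of the 13 lower genes were detected on no Day 56 array. Neither can be told apart from a lasting effect of injury, since all Day 56 arrays have a high background and all controls a low one.

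Other splits of the 6 samples of a comparison make 10 with the real one, so a share under 0.05 cannot be reached. By limma, the real split called 0 genes for Day 2 against control, and 10 of 10 splits called as many, the highest 203; that split set Control replicates 1 and 2 and Day 2 replicate 2 against the rest, which points to a structure of the samples. For Day 7 against control the real count was 100 and the highest other 0, with 1 split as large; for Day 28, 0 and 0, with 10; for Day 56, 20 and 0, with 1. Between times the real and highest other counts were 0 and 71 for Day 7 against Day 2 (10 as large), 0 and 1 for Day 28 against Day 7 (10), and 0 and 1 for Day 56 against Day 28 (10). The split with 71 genes set Day 2 replicates 1 and 3 and Day 7 replicate 1 against the rest.

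For lists past camera the real count and the highest of the other splits were 5 and 17 at Day 2 (9 splits as large), 10 and 16 at Day 7 (6), 6 and 14 at Day 28 (8) and 5 and 15 at Day 56 (9), each against control. They were 14 and 16 for Day 7 against Day 2 (2), 12 and 14 for Day 28 against Day 7 (4) and 2 and 8 for Day 56 against Day 28 (5). For the 12 genes that differed among the 5 groups, 3 of 100 drawn assignments, the real one included, gave as many, the highest other 426. That share lies under 0.05 but is not corrected for the other counts of splits, so chance is not excluded. The count was also 0 with the authors' quantile values and without background correction. Drawn assignments cannot separate group from background set, which nearly coincide.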

How the results depend on the processing

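The background block, random block, fits within a background set and the Y-linked covariate were chosen after the data were seen. By limma, genes changed at Day 7 (100), at Day 56 (20) and among the 5 groups (12, F) had these counts under other settings: authors' quantile values, Day 56 0, F 0; median scaling, Day 7 2.5e+02 (140 higher, 106 lower), Day 56 1, F 2; no background correction, Day 7 64, Day 56 0, F 0. No detection filter gave Day 7 5, Day 56 108 (58 higher, 50 lower), Day 7 against Day 2 1, Day 28 against Day 7 1, Day 56 against Day 28 4 and F 26. Detection on at least 8 arrays gave Day 56 5 and F 0, every probe Day 56 62, and trend with robust options Day 56 0 and F 0. A fit to the 2 groups alone gave Day 7 202, Day 28 1 and Day 56 46. Array weights, in which Control replicate 1 weighed 5.03, gave Day 2 2295, Day 7 1169, Day 28 716, Day 56 1397, Day 56 against Day 28 3 and F 3007. The replicate block gave Day 7 1, Day 56 2, Day 28 against Day 7 1, Day 56 against Day 28 1 and F 0; 12 of 30 same-number correlations of deviations were over 0.1, so the numbers are not read as pairs, while 9 of 15 samples lay closest to their own number, against 5 on average over 1296 renumberings (exact permutation, one-sided, p 0.0849). The background block gave Day 7 3, Day 56 1, Day 7 against Day 2 3, Day 28 against Day 7 7 and Day 56 against Day 28 1; the random block (correlation 0.119) Day 7 54 and Day 56 1; low-background arrays Day 7 0; high-background arrays Day 28 against Day 7 157. The high-background arrays hold 1 Day 7 sample, replicate 3, without a spread of its own. Their count for Day 28 against Day 7 is thus not read as a number of changed genes. The Y-linked covariate gave Day 7 0, Day 56 9 and F 0. By the authors' criterion, 2-fold and an unadjusted p of a two-sample test on their log2 values in place of limma, there were 4, 194, 28 and 32 genes for Day 2, 7, 28 and 56, and 34, 129 and 12 between times; with that test's p adjusted, Day 7 0 and Day 56 0. Of 54 lists past camera, 0 passed with an estimated correlation and 2 with fry. Of the 36 named genes past the threshold, 17 passed with the authors' values, 21 with median scaling, 15 without background correction and 0 with the background block. The overlap of changes was 2, and 275 at an unadjusted p under 0.01. The cause was not tested, except for the 20 Day 56 genes with the background block, where the median SE went from 0.201 to 0.360. With 1 sample left out (normalized values kept, spread pooled) the ranges were 0 to 508 at Day 2, 0 to 330 at Day 7, 0 to 0 at Day 28, 1 to 26 at Day 56, 0 to 3 for Day 7 against Day 2, 0 to 18 for Day 28 against Day 7, 0 to 1 for Day 56 against Day 28, 0 to 784 for F, 50 to 71 lists and 1 to 36 named genes, where genes of comparisons without that sample count as passing. List medians turned with the background block for injured tubule at Day 28 (-0.56) and endothelium from Day 7 to Day 28 (-0.57), without Control replicate 2 for cell cycle at Day 28 (0.15, with -0.60 the lowest with 1 sample left out) and Day 56 (-0.0327, by the test's direction; lowest -0.73), and without Day 2 replicate 2 for complement (-0.0168, highest 0.71) and macrophage markers (-0.19, highest 1.81) from Day 2 to Day 7; the cause was not tested. Directions of the 100 Day 7 genes and the 20 Day 56 genes held under the settings where they were compared, which is nearly fixed for genes picked on the same arrays. Lists past camera kept direction and threshold in 53 of 54 with the authors' values and without background correction, 54 with the replicate block, 44 with the background block and 46 with the covariate. Median scaling moved the median of all genes to -0.40 at Day 56, -0.30 from Day 28 to Day 56, -0.108 at Day 2 and -0.105 at Day 28, so differences there are relative to that. A slide block was not run, since the files used here do not name slides. Signal over background limits dim genes: the high-background arrays detected as few as 8337 probes.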

Other observations

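The genes below were chosen after the result was seen, from the 100 that passed at Day 7, and no test was run on them as groups.

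Genes of lipid and lysosome handling were among those higher at Day 7 by limma. Apoe, the lipid carrier of macrophages and other cells, had a log2 difference of 4.11 ± 0.60 (SE). Soat1, which esterifies cholesterol, had 1.73, Npc2, which moves cholesterol out of lysosomes, 1.17, the lysosomal phospholipase gene Pla2g15 1.71 and Trf, the iron carrier transferrin, 3.61 (4.27 without Control replicate 1). Bmp1, which trims procollagens, had 1.84 and the collagen gene Col16a1 1.73. The macrophage elastase gene Mmp12 was at least 13.4-fold brighter than in controls (22.4-fold without Day 7 replicate 2), Tnfrsf11b, a decoy receptor for RANK ligand, at least 1.64-fold, and the ribonuclease paralogs Ear4 and Ear10 at least 1.70-fold and 1.13-fold.

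Genes of salt and calcium handling were among those lower at Day 7. The kinase genes Wnk1 and Wnk4, which regulate distal sodium chloride transport, had log2 differences of -1.16 and -1.17 and Casr, the calcium-sensing receptor, -1.77, while the tight junction gene Cldn11 was at least 1.98-fold dimmer. The kallikrein genes Klk1, Klk1b4 and Klk1b5 had -1.21, -2.22 and -2.05, and as close paralogs their probes may share signal.

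The probes of the Y-linked genes Eif2s3y and Kdm5d were both detected on each array except Control replicate 1, Day 2 replicates 1 and 2 and Day 28 replicate 3, where 0 of the 2 were. On these 4 arrays Ddx3y, also Y-linked, had log2 signals of 9.46, 10.10, 9.68 and 10.94, against 10.97 to 11.97 on the others. Uty, Y-linked too, had 5.39, 5.24, 5.04 and 5.07, against 5.72 to 6.86. Xist, transcribed from the inactive X chromosome, was detected on all of these 4 arrays but Day 2 replicate 1, and on no other array. Sex-linked signal thus differed within groups and was not balanced between them. Ccl5, Gadd45a, Uhrf1 and Vegfa each belong to 2 of the gene lists.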
